A study of Arabidopsis thaliana with 12 samples.

How the data were processed

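Total RNA of Arabidopsis thaliana Columbia 0 was measured on 12 arrays, 6 from plants at 20 °C and 6 from plants held for 24 h at 4 °C, per the labels. The table the authors deposited gives 1 intensity per probe and array on a linear scale. The scanner, background correction and scaling are not given in the sources used here. The values themselves show that the deposited intensity was already scaled, since the mean per array was between 1.02 and 1.09 and lay within 5% of the overall mean on every array. No value was below 0 or above 100, 9 of the 12 arrays held a probe at 100, and each array listed between 154 and 226 probes at 0. The median per array was between 0.536 and 0.569 at 20 °C and between 0.276 and 0.315 at 4 °C. The 10 brightest probes held 13.1% to 13.9% of the summed intensity at 20 °C and 19.2% to 20.1% at 4 °C. The precision is limited by the number of arrays and pairs, and for the dimmest probes by values near 0. A change is relative to each array's own total rather than to an amount of RNA.

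Probes were named from the platform annotation, updated through gene identifiers to the symbols of the reference assembly GCF_000001735.4 TAIR10.1. Of 3439 probes, 692 had 1 gene name, 690 of which matched a reference locus, 870 had several and 1877 had none here. Only single-name genes are named. No coordinates are given, since no build is stated for the array. The 2 probes of 1 gene were averaged, which left 3438 features, called probes in the text, and 689 named genes.

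Because the means agreed within 5%, the intensities were used as deposited, by a rule fixed before the data were examined, and transformed to log2. Values of 0 were set to the lowest value above 0 on that array. The 60 features at 0 on all 12 arrays received calls from these floors alone, so calls were counted over the 3378 others, while the Benjamini-Hochberg adjustment ran over all 3438. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, at an adjusted p of 0.05, 4 °C minus 20 °C. A fold is 2 to the power of the size of the log2 change, so it is a ratio of geometric means and can differ from the ratio of the printed means. No fold is given for genes listed at 0 on any array.

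Replicates were compared before averaging. In each group the ratio of the mean square between pairs to that within pairs was highest for arrays 1-2, 3-4 and 5-6 among the 15 ways to pair 6 arrays, with a median of 11.8 at 20 °C and 5.07 at 4 °C. Whether both arrays of a pair read the same RNA is not given in the sources used here. The 12-array test was fixed before the data were examined, and its p-values are too small if the pairs are technical repeats, so the fit on pair means stands beside it. Means and SDs are over 3 pair means of linear intensities, and the SE of a log2 change comes from the fit on pair means. The words rose and fell are used for named genes past the threshold in both fits, unless the pair-mean result is given.

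On simulated data built from the real means and spreads of 3108 probes in 20 runs, with 200 probes changed by 1 and 200 by 2 on the log2 scale, the 12-array fit recovered 88.8% and 97.2% of the changed probes and called 7.27% of the unchanged ones. The fit on pair means recovered 69.7% and 89.8% and called 0.958%. Of all calls in these simulations, 34.6% were false with 12 arrays and 7.50% with pair means. These shares depend on how many probes were set to change, so they cannot be carried over to the measured calls.

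Gene lists were tested with camera at a preset correlation of 0.01, on lists with at least 3 measured members, adjusted over the lists of a kind. camera with an estimated correlation and fry were run beside it. The 23 lists of the first kind were fixed before the data were examined. Their members whose listed symbol belongs to another locus were left out. The 11 lists of the second kind were drawn up afterwards, when some of the brightest values had been seen but no list had been tested. They came from the names of the measured genes, apart from the photosynthesis list. That list joins the fixed antenna, photosystem, electron transport and Calvin cycle lists. The genes named are the 8 largest rises and 8 largest falls among those past the threshold with non-overlapping groups, restricted to genes above 0 on all arrays, up to 4 members per list past the threshold by size or, where fewer than 2 passed, up to 2 by p, and a fixed set of 10 cold and light markers. PSB27 is named in addition, to complete the photosystem II list. XERICO, of the stress, calcium and sugar list, is also named outside this rule, while other members of its list stay unnamed. The genes named under Other observations were chosen after their values were seen.

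Alternatives were median centring, quantile normalization, cyclic loess, leaving out the 860 dimmest probes, an offset of 0.0680 before log2, a trended robust variance, the replicate number as a block, pair means in either of 2 pairings, a minimum fold of 2, and each array left out. Added after seeing the data were pair means under each scaling, both arrays of a pair left out, and counts with all probes at 0 or with none.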

Results

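The series measured transcript levels with arrays in wild-type Arabidopsis thaliana, the thale cress, of the ecotype Columbia 0. One group of 6 arrays came from plants kept in medium light at 20 °C. The other group of 6 came from plants that spent 24 h at 4 °C in that light, a condition the submitters describe as photoinhibitory, that is, one in which light damages photosystem II faster than it is repaired. The table held 3439 probes. Of these, 692 carried 1 gene name, 870 carried several and 1877 carried none in the annotation used, so the named results cover 689 genes. Within each group, arrays 1 and 2, 3 and 4, and 5 and 6 were far more alike than any other pairing, and each such pair was counted as 1 sample, so means and SDs below have n = 3 per group. Nothing in the labels says whether the 3 pairs of a group were separate plants. The p-values over pair means therefore measure only the spread between these samples, which may be technical. Those over the 12 arrays count each array as a sample, so they also draw on the smaller spread within pairs. They are too small if the pairs are technical repeats. The number of pairs limits the precision.

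The comparison asked which genes differed in level between plants at 4 °C and at 20 °C in the same light. Most probes had lower deposited intensities at 4 °C. AT5G48130, a member of the NPH3 family of phototropism-related proteins, fell from 0.409 ± 0.00391 at 20 °C to 0.0320 ± 0.0321 at 4 °C (SD, n = 3). The level at 4 °C is low and varied as much as its mean, so the size of this fall is uncertain. Its log2 change was -4.36 ± 0.77 (SE) as deposited, -2.51 after quantile normalization and -2.30 with an offset of 0.0680 added before log2. AT4G39570, a Kelch-repeat F-box protein, fell 8.91-fold, from 1.14 ± 0.128 to 0.133 ± 0.0331, and its log2 change of -3.16 became -2.38 after quantile normalization. In the other direction CML30, a calmodulin-like protein, rose 2.53-fold, from 1.23 ± 0.0607 to 3.15 ± 0.628, and MAMI, a membrane-associated protein known to respond to mannitol, rose 2.67-fold, from 0.607 ± 0.296 to 1.48 ± 0.335.

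Of the 3378 probes above 0 on at least 1 array, 2442 passed an adjusted p of 0.05 in limma over the 12 arrays, 420 of them higher and 2022 lower at 4 °C. With pair means in place of single arrays, 1907 passed, 232 higher and 1675 lower. A change of at least 2-fold was seen with the call in 87 probes that were higher and 1303 that were lower. The median log2 change over the 3378 probes was -0.74. The split between higher and lower depended on how arrays were scaled to each other. It was 1335 higher and 896 lower after median centring, 1084 and 1028 after quantile normalization, and 1039 and 1038 after cyclic loess, with median log2 changes of 0.17, 0.05 and -0.0005. In the 8 fits made from these 4 scalings with 12 arrays or pair means, 170 probes were called higher every time and 506 lower every time, among them 29 and 99 genes with a single name. A gene described below as having risen or fallen, without a statement that it did so in all 8 fits, missed the threshold or changed sign in at least 1 of them.

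**Figure D1:**
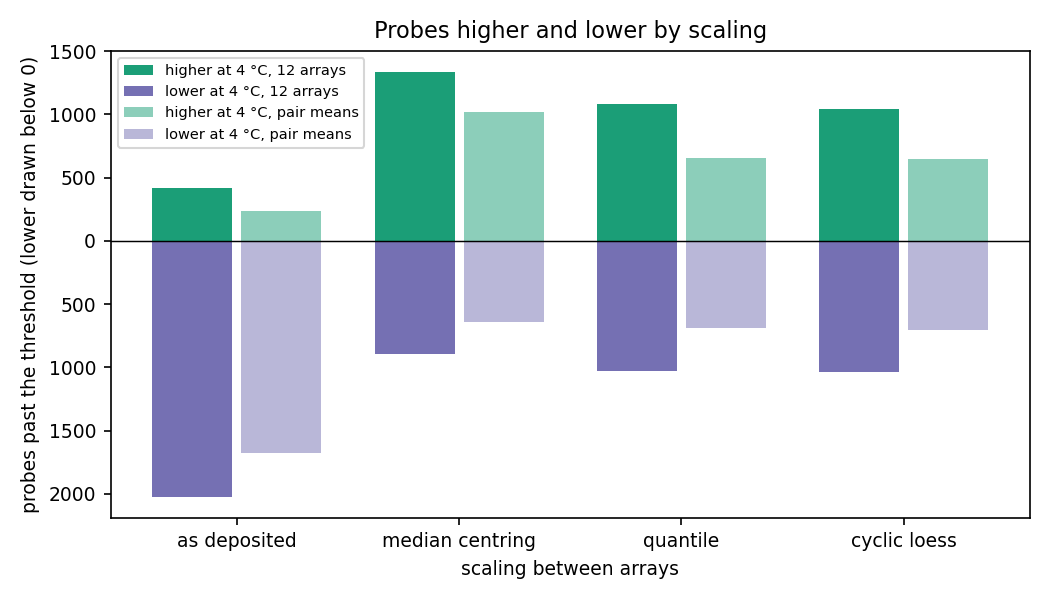
Probes past an adjusted p of 0.05 (y axis, number of probes) that were higher or lower at 4 °C, for each scaling between arrays (x axis), with dark bars for 12 arrays and pale bars for pair means. As deposited, 2022 probes were lower and 420 higher, while cyclic loess gave 1038 and 1039.

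The 8 largest rises among single-name genes measured on all 12 arrays were in AT1G02020, AT2G21530, MAMI, AT4G17070, CML30, AT3G57630, AT1G78620 and AT2G31800. Their folds ran from 2.32 to 3.42, and each passed in both the 12-array fit and the pair means. AT1G02020 rose from 0.334 ± 0.0304 to 1.38 ± 1.03, with an adjusted p of 0.038 over pair means. Its first place rests on arrays 1 and 2 at 4 °C, without which its log2 change was 1.19, below AT2G31800 at 1.35, AT2G21530 at 1.28 and others. Without arrays 1 and 2 at 20 °C the log2 changes of MAMI and AT4G17070 went from 1.42 and 1.37 to 0.91 and 0.88. AT2G21530 rose from 0.435 ± 0.0686 to 1.18 ± 0.259 (adjusted p = 0.0033 over pair means). AT3G57630, an exostosin-family glycosyltransferase, rose from 0.781 ± 0.0682 to 1.94 ± 0.416. AT2G31800, a protein kinase, rose from 0.149 ± 0.0197 to 0.352 ± 0.0509, with array 2 at 4 °C below the other 5. AT4G17070 was the brightest of the 8, at 19.4 ± 10.2 and 45.4 ± 9.50, and its call was lost after quantile normalization of pair means (adjusted p = 0.27, log2 change 0.77). The other 7 were higher in all 8 fits, with log2 changes of 1.44 to 2.47 after quantile normalization.

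The 8 largest falls were in AT5G48130, AT4G38670, AT2G31920, AT1G25500, AT3G59300, AT3G01060, AT4G39570 and AT5G06930, with log2 changes from -4.36 to -3.15 as deposited. All 8 were lower in all 8 fits, but after quantile normalization their log2 changes ran only from -2.67 to -1.69 and the order changed, with AT4G38670 first. AT4G38670, a thaumatin-family protein, fell from 0.914 ± 0.328 to 0.0840 ± 0.0631. Its log2 change of -3.94 was -3.06 without arrays 1 and 2 at 4 °C and -4.61 without arrays 3 and 4 at 4 °C, and that of AT5G48130 was -3.73 and -5.25. AT2G31920 fell 12.3-fold to 0.0892 ± 0.0354, a log2 change of -3.62 ± 0.35 (SE). AT5G06930, the brightest of the 8 at 20 °C, fell from 1.88 ± 0.258 to 0.230 ± 0.102. AT3G01060 fell from 0.399 to 0.0571, with array 1 at 4 °C below the other 5. Relative to the median change of all probes, these 8 genes lay between -3.62 and -2.40 on the log2 scale, and the 8 largest rises between 1.96 and 2.52.

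**Figure D2:**
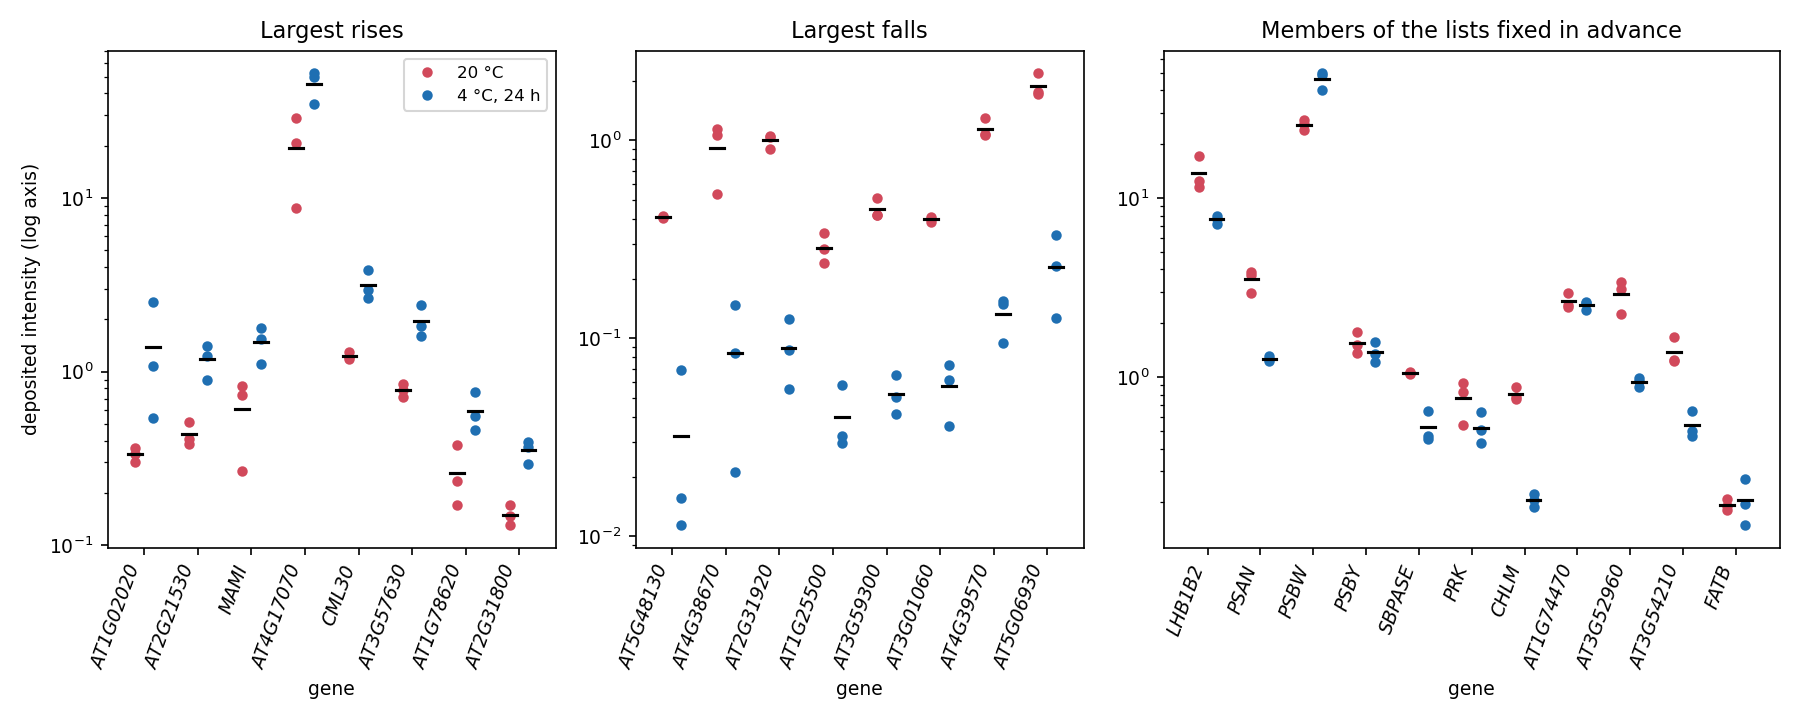
Deposited intensity (y axis, log scale) of the genes with the largest rises, the largest falls and the measured members of the lists fixed in advance that the text names, apart from PSB27 (x axis). Each point is the mean of a pair of arrays, red at 20 °C and blue at 4 °C, and the black bar is the mean of 3 pairs. CHLM falls from 0.806 to 0.207 and PSBW lies at 25.7 and 46.1, a rise that quantile normalization and cyclic loess reduced to log2 changes of 0.20 and 0.16.

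Genes of photosynthesis did not move together as deposited or after median centring. Photosystem II subunits were the only list fixed in advance with at least 3 members that were measured and kept. PSBW, a small subunit of photosystem II, rose 1.79-fold, from 25.7 ± 1.69 to 46.1 ± 5.38, and passed in the 12-array and pair-mean fits but not after quantile normalization of pair means (adjusted p = 0.28). PSBY stood at 1.55 ± 0.216 and 1.38 ± 0.177, and PSB27, an assembly factor of the complex, at 4.53 ± 2.97 and 5.06 ± 2.67. Neither passed the test. Thus 1 of 3 members rose and 0 fell, and the same counts held adjusted over the list alone. As a list they lay 1.24 above the mean log2 change of all probes in camera (adjusted p = 0.048), and the call was lost with an estimated correlation (adjusted p = 0.074) and after quantile normalization (adjusted p = 0.73).

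Other photosynthesis genes were measured in lists with 1 or 2 members on the array. PSAN, a lumenal subunit of photosystem I, fell 2.77-fold, from 3.52 ± 0.485 to 1.27 ± 0.0381, and was lower in all 8 fits. LHB1B2, a light-harvesting chlorophyll-binding protein of photosystem II, fell from 13.7 ± 3.04 to 7.63 ± 0.392 as deposited, a log2 change of -0.83 that became 0.08 after median centring. It belongs to a family of near-identical copies, so its probe may also bind their transcripts. In the Calvin cycle, SBPASE, sedoheptulose-bisphosphatase, fell from 1.06 ± 0.0128 to 0.525 ± 0.109. PRK, phosphoribulokinase, had 0.765 ± 0.199 and 0.524 ± 0.105, and its pair means did not pass (adjusted p = 0.14). In the 12-array fit, 2 of the 2 Calvin cycle genes passed adjusted over all genes, and therefore by construction also adjusted over the list alone. After quantile normalization of pair means PSAN, LHB1B2 and SBPASE passed as lower, at log2 changes of -1.50, -1.23 and -0.42. PSBW, PSBY and PRK did not pass there, and cyclic loess gave the same calls. With median centring of pair means PSAN passed as lower and PSBW and PSBY as higher.

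**Figure D3:**
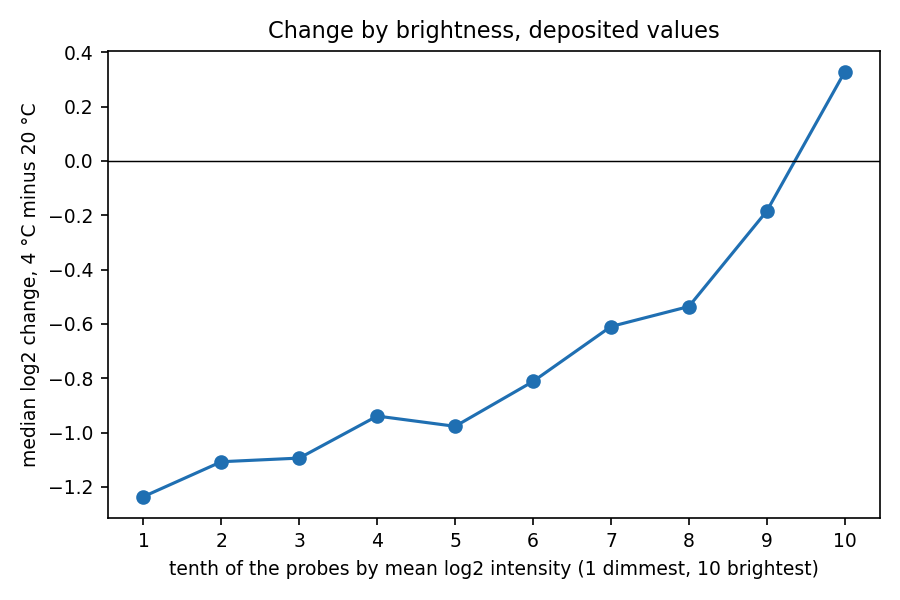
Median log2 change at 4 °C against 20 °C (y axis) in each of 10 equal groups of the probes above 0 on all arrays, ordered by mean log2 intensity (x axis, dimmest first). The medians run from -1.24 in the dimmest group to 0.33 in the brightest.

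The size of the change moved with brightness. With the probes above 0 on all arrays split into 10 equal groups by mean intensity, the median log2 change was -1.24 in the dimmest group and 0.33 in the brightest, and 72.3% of the brightest group had higher values at 4 °C. PSBW, LHB1B2 and AT4G17070 were among the brightest named genes, and the scalings that remove this trend moved their log2 changes to 0.20, -1.23 and 0.77 with quantile normalization.

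In chlorophyll synthesis CHLM, the magnesium-protoporphyrin IX methyltransferase, fell 3.92-fold from 0.806 ± 0.0637 to 0.207 ± 0.0166, was lower in all 8 fits and lay 1.22 below the median change of all probes on the log2 scale. AT1G74470, geranylgeranyl reductase, had 2.65 ± 0.272 and 2.53 ± 0.137 and did not pass, so 1 of 2 members of this list fell, also when adjusted over the list alone. AT3G52960, a plastid type II peroxiredoxin of the antioxidant list, fell 3.07-fold, from 2.93 ± 0.593 to 0.943 ± 0.0545, again in all 8 fits. AT3G54210, a plastid ribosomal protein, fell 2.57-fold, from 1.38 ± 0.254 to 0.539 ± 0.0959. FATB, an acyl carrier protein thioesterase of fatty acid synthesis, had 0.194 ± 0.0143 and 0.205 ± 0.0618 and did not pass. Under each other scaling of pair means it passed as higher, at log2 changes of 0.95 with median centring, 1.22 with quantile normalization and 1.16 with cyclic loess. The single members kept of the antenna, photosystem I, antioxidant and ribosomal lists passed adjusted over the list alone, and FATB did not. With 1 member this is the unadjusted p, so a gene that passed over all genes had to pass here.

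Of the 365 entries in the 23 lists fixed in advance, 12 were measured on a single-name probe and kept. Another 4, all on the plastid ribosomal list, were measured but left out for a conflicting symbol, so that list was not tested. Of the lists, 15 had no member measured on a single-name probe. The cold-regulated and early light-induced genes were among those. COR15A, COR15B, COR47, KIN1, KIN2, ELIP1, ELIP2, PSBS, CHS and FSD1 had no single-name probe in the annotation used. Transcripts of these genes may still have been measured on probes with several gene names, which were not used for the lists.

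A further 11 lists were drawn up before their changes were tested, when some of the brightest values had been seen. They came from the names of the measured genes, apart from the photosynthesis list, which joins lists fixed in advance. None of the 11 passed camera after adjustment over them, so none of them is shown to differ from the other probes. Among all 674 single-name genes above 0 on at least 1 array, 424 were lower and 74 higher in the 12-array fit. With pair means these counts were 350 and 40, and the member counts below should be read against them. Pentatricopeptide repeat proteins, RNA-binding proteins of plastids and mitochondria, had 12 of 18 members lower and 1 higher. AT1G79080 fell from 0.813 ± 0.0436 to 0.210 ± 0.0320 and was lower in all 8 fits, and AT2G17670 fell from 1.08 ± 0.438 to 0.299 ± 0.0455. AT3G51320 had a mean of 0.116 ± 0.0197 at 20 °C and was listed at 0 on 3 of the arrays at 4 °C. Of the 6 mTERF proteins, relatives of a transcription termination factor, 5 fell, led by AT1G61990 from 0.880 ± 0.0660 to 0.152 ± 0.0228 and AT1G62010 from 0.896 ± 0.0789 to 0.239 ± 0.0329, both lower in all 8 fits. With pair means 11 and 4 members of these 2 lists were lower.

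Of 6 redox and antioxidant factors, 5 fell as deposited. Among them were SRX, sulfiredoxin, from 0.262 ± 0.0664 to 0.0760 ± 0.0129, and GLDH, the last enzyme of ascorbate synthesis, from 0.402 ± 0.0544 to 0.185 ± 0.0198. In pair means GLDH passed under no other scaling, at log2 changes of -0.21 with median centring, -0.08 with quantile normalization and -0.06 with cyclic loess. SRX passed there with median centring only, at -0.90, against -0.52 with quantile normalization and -0.60 with cyclic loess. CCS, the copper chaperone of superoxide dismutase, fell by 0.85 on the log2 scale as deposited, with values of 0.06 to 0.18 under the other scalings. Of 6 genes of the chloroplast NDH complex and its assembly or RNA editing, 4 fell as deposited. PIFI fell from 0.228 ± 0.0352 to 0.0447 ± 0.0297 and CRR21, an RNA editing factor, from 0.980 ± 0.164 to 0.485 ± 0.00633. PIFI and CRR21 passed in pair means under no other scaling. With median centring, quantile normalization and cyclic loess, PIFI stood at -1.81, -1.14 and -1.37 on the log2 scale and CRR21 at -0.09, -0.36 and -0.39. CRR41 and NdhN had log2 changes of -0.65 and -0.59 that were above 0 under each other scaling. Among 7 assembly and translation factors of the photosynthetic complexes, 4 were called lower in the 12-array fit and 3 in pair means. ATAB2 fell from 0.172 ± 0.0198 to 0.0510 ± 0.00169. Its log2 change of -1.82 became -0.36 after quantile normalization, where its pair means passed (adjusted p = 0.038). LPA19 had 0.622 ± 0.00779 and 0.468 ± 0.0741, was not called in pair means (adjusted p = 0.065) and was above 0 under the other scalings.

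In tetrapyrrole and carotenoid synthesis, 3 of 5 genes fell. Besides CHLM these were SIRB, from 0.338 ± 0.0562 to 0.138 ± 0.0134, and Z-ISO, the 15-cis-zeta-carotene isomerase, which had 2.33 ± 0.367 at 20 °C and 0.0534 ± 0.0709 at 4 °C, where 2 of the 6 arrays listed it at 0. The list of stress, calcium and sugar responsive genes was split, with 4 members higher, 3 lower and 1 not called, or 3, 3 and 2 in pair means. XERICO, a RING-type protein linked to abscisic acid, rose from 3.42 ± 0.251 to 6.38 ± 0.617 and was higher in all 8 fits, alongside CML30 and MAMI, while SIS fell from 0.389 ± 0.0990 to 0.119 ± 0.0607. Its camera p was 0.0095 before and 0.10 after adjustment.

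All 4 measured GH9B endoglucanases, enzymes of cell wall loosening, fell as deposited, by 2.96-fold to 3.94-fold, and GH9B11 was lower in all 8 fits, from 0.718 ± 0.0167 to 0.198 ± 0.0591. Of 5 regulators of reproductive organs, measured as markers of other organs, 4 fell, including SPL from 0.691 ± 0.0269 to 0.287 ± 0.0154 and AGL54, lower in all 8 fits, from 0.248 ± 0.0274 to 0.0574 ± 0.0195. Of 4 histone H3 and cell cycle genes, 2 fell as deposited: the histone gene AT1G09200 from 0.273 ± 0.0725 to 0.112 ± 0.0451 and FBL17 from 0.341 ± 0.00938 to 0.162 ± 0.0215. After cyclic loess FBL17 stood at 0.01 on the log2 scale. The 7 photosynthesis genes taken as 1 list had 1 member higher, 4 lower and 2 not called, with a camera adjusted p of 0.87.

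The median, mean and camera direction differed in sign in 3 of these lists. Relative to all probes, the assembly factors had a median of 0.31 and a mean of 0.26 against a downward test, the histone and cell cycle genes a median of -0.13 and a mean of 0.20 against a downward test, and the pentatricopeptide repeat proteins a median of 0.05 and a mean of -0.05 against a downward test. fry asks only whether the members move one way on balance and takes no account of the general fall. Over single arrays it gave adjusted p-values of 5.4e-05 or less for each of the 11 lists. It was not run on pair means, so these p-values are too small if the pairs are technical repeats.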

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

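The tests of the arrays' pairing and of the trend with brightness were chosen only after the result was seen, while those on other splits of the samples and on the photosynthesis genes were planned. Among the 60 genes named by rule and 3 measures per array, tested in both groups, 2 of 126 sets of 6 arrays held 1 array far from the others. Chance gives about 1 in 20 for independent values. Arrays here came in alike pairs, so the count cannot be compared with that rate. For AT2G31800 at 4 °C, array 2 read 0.205 against 0.337 to 0.451 on the other 5, a gap of 0.632 of the range. For AT3G01060 at 4 °C, array 1 read 0.00693 against 0.0423 to 0.0977, a gap of 0.684 of the range.

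The first pattern is the pairing of arrays 1-2, 3-4 and 5-6. Both arrays of a pair may have read the same hybridisation: the mean square between pairs was 5.07 times that within pairs at 4 °C and 11.8 times at 20 °C, and no other of the 15 pairings gave a higher ratio in either group. Correlations of the log2 values across probes were 0.991 to 0.994 within pairs at 20 °C and 0.962 to 0.973 at 4 °C. Separate plants that shared a day or an extraction stay open. No biological explanation was tested.

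The second pattern is the general fall, stronger in dim probes. A single factor per array gives all probes of an array the same log2 shift, so by its construction it cannot account for the trend with brightness, in which the median log2 changes of the brightest and dimmest of 10 groups of probes lay 1.56 apart (95% bootstrap interval 1.43 to 1.75). A constant taken alone from every probe at 4 °C is argued against, since the median loss in the seventh group was 2.74 times that in the dimmest (2.04 to 3.46). A constant as large as the loss of 0.268 there would take to 0 the 713 probes that lay below it at 20 °C, while 181 to 226 per array were listed at 0. Probes at 0 are not the cause, as the median change without them was -0.70 (-0.74 to -0.65). These intervals come from resampling probes with the arrays held fixed, so they do not measure the spread between samples. For the general fall alone, though not for its trend with brightness, the scaling to a common mean stays open, since it lowers all other probes when the brightest take more of the signal. For both, a scanner or labelling response that differs with brightness, and lower levels of most transcripts at 4 °C stay open. A constant taken before the scaling to a common mean was not tested and stays open as well.

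The third pattern is the count of probes past the threshold. Of 100 splits of the 12 arrays into 6 and 6, only the real one, 1, gave as many as 2442, and the highest of the others gave 0. Arrays of a pair were far more alike than other arrays, so splits of single arrays cannot decide whether chance is excluded. With the 6 pair means there are 10 splits, of which 1, the real one, gave 1907 and the highest other 0, but 10 splits are too few for a share under 0.05.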

How the results depend on the processing

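The total of 2442 probes stayed within 1.5 times under median centring, quantile normalization, cyclic loess, the filter, the offset, the trended variance and both pairings, but the split did not. Where no construction is named below, the cause was not tested. Higher and lower were 1335 and 896 after median centring, 1084 and 1028 after quantile normalization, and 1039 and 1038 after cyclic loess. A minimum fold of 2, which calls fewer by construction, left 1390, 87 higher and 1303 lower. Pair means of arrays 1-2, 3-4 and 5-6 left 232 higher. The settings with both choices, or with a pair left out, were chosen after seeing the data. Pair means gave 1015 and 638 with median centring, 658 and 692 of 1350 with quantile normalization, and 646 and 703 of 1349 with cyclic loess. In pair means without arrays 1-2, 3-4 or 5-6 at 20 °C, 165, 166 and 142 were higher, the last of 1525 in all, and without those pairs at 4 °C, 191, 160 and 210; fewer samples were fitted. With 1 array left out the total ran from 2356 to 2430, with 406 to 421 higher and 1950 to 2024 lower. Counting probes at 0 on all arrays gave 2502.

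The replicate number as a block gave 2419 calls. Same-numbered arrays had deviation correlations of -0.11 and -0.087 for numbers 1 and 2, and of 0.12 to 0.15 for numbers 3 to 6. Arrays 3 and 4 alone correlated best with their own number, so a pairing across groups by number is not shown. In the block the shift of the photosystem II list, 1.24, missed the threshold (adjusted p = 0.074).

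That list kept its direction under each alternative. It missed the threshold at an unchanged 1.24 with median centring, an estimated correlation and pairs 1-4, 2-5 and 3-6, and at 0.14 with quantile normalization, 0.13 with cyclic loess, 0.95 without the 860 dimmest probes and 1.05 with probes above 0 on all arrays. It also missed it at 1.06 without arrays 1-2 and, over 12 arrays, at 1.37 without arrays 5-6 at 20 °C, and at 1.08 and 1.15 without arrays 1-2 and 5-6 at 4 °C. With 1 array left out it lay between 1.16 and 1.34 and missed the threshold without array 1 or 2 at 20 °C or array 1, 2 or 5 at 4 °C, and its adjusted p ran from 0.021 to 0.89 over all alternatives. No other list passed, except the stress list without the 860 dimmest probes (1.13) or without arrays 1-2 at 20 °C (0.70). Mean shifts relative to all probes changed sign for photosynthesis (-0.34 with quantile normalization and -0.34 with loess), histones (-0.042 to 0.42 with 1 array left out, below 0 without array 1 at 4 °C, and -0.32 with probes above 0), pentatricopeptide proteins (-0.13 to 0.041 with 1 array left out, above 0 without array 3 or 4 at 4 °C, 0.15 without both and 0.022 with probes above 0) and NDH (-0.050 with probes above 0).

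Of the 60 genes named by rule, which leave out PSB27, XERICO and those under Other observations, 57 passed. Of the 60, 20 kept sign and side of the threshold under every alternative run, 36 lost their call under at least 1, and 12 changed sign under at least 1. With median centring these were LHB1B2 (0.084), PSBY (0.74), PRK (0.39), AT1G74470 (0.85), CRR41 (0.26), NdhN (0.32), AT1G22700 (0.23), LPA19 (0.49) and CCS (0.063). With quantile normalization they were PSBY (0.023), PRK (0.18), CRR41 (0.11), NdhN (0.46), LPA19 (0.37), CCS (0.12) and AILP1 (1.12). With cyclic loess they were PRK (0.16), CRR41 (0.10), NdhN (0.48), LPA19 (0.36), CCS (0.18) and FBL17 (0.012). FATB ran from -0.082 to 0.15 with 1 array left out, below 0 without array 1 or 2 at 4 °C, and stood at -0.19 without both and at -0.0089 without arrays 5-6 at 20 °C, and AT1G74470 at 0.015 without arrays 1-2 at 20 °C. Of the 3 that had not passed, FATB passed as higher under each other scaling with 12 arrays or pair means (0.95, 1.22 and 1.16), AT1G74470 as lower with quantile normalization and loess over 12 arrays, and PSBY as lower in the replicate block and without arrays 1-2 at 4 °C, while both passed as higher with median centring. Signal near 0 limits the dimmest genes, and the log2 values of Z-ISO, AT3G51320 and AILP1, each listed at 0 on at least 1 array, rest partly on the floor.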

Other observations

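The genes in this paragraph were chosen after their values were seen, from the 29 higher and 99 lower in all 8 fits. AT-HF, an enzyme of histidine synthesis, rose from 1.11 ± 0.0790 to 2.39 ± 0.588 (SD, n = 3), and AT4G17260, a lactate dehydrogenase, from 0.450 ± 0.0189 to 0.714 ± 0.177. ETFQO, an electron-transfer flavoprotein oxidoreductase of mitochondria, fell from 0.497 ± 0.0443 to 0.0927 ± 0.0357. SECE1, a subunit of the thylakoid protein translocase, fell from 0.970 ± 0.0174 to 0.220 ± 0.0601, and TCP15, a growth-regulating transcription factor, from 0.671 ± 0.0951 to 0.204 ± 0.0385.

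Among probes above 0 on at least 1 array, 78 were listed at 0 on all 6 arrays at 20 °C only and 14 on all 6 at 4 °C only, although more probes per array were at 0 at 4 °C.

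One hypothesis, written down before its result, was that photosynthesis genes stand above other probes at 4 °C only because they are bright. The median log2 change of the 7 measured genes was -0.53, which is 0.22 above the median of all probes but lies at percentile 3.62 of 10000 random lists matched on brightness, whose median was 0.14 (95% between -0.64 and 0.71). The small lead over all probes may therefore come from brightness, and against equally bright probes these genes lay on the low side without leaving the range set in advance.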
